A study of Homo sapiens with 60 samples.

How the data were processed

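CUT&RUN, an assay that cleaves chromatin where an antibody is bound and sequences the released fragments, was run on PC9 cells, a human lung adenocarcinoma line. There were 3 genotypes: wild type (WT), METTL7A knockout (KO), and knockout cells that overexpress tagged METTL7A (Rescue). Each was untreated or grown under osimertinib, an EGFR inhibitor whose dose was raised from 100 nM over 6 to 8 weeks, per the labels. With 5 antibodies (H2A, IgG, H3K27Ac, RAD21 and PDS5A) this gave 30 groups of 2 samples, 60 samples in all. The 12 H2A samples were not used here, so 48 samples stood behind the 24 peak lists analysed.

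Per the submitters' processing notes, the tools were Trimmomatic, FastQC, Bowtie2 2.4.2, SAMtools 1.16, MACS2 2.2.7.1, bedtools 2.30 and deepTools 3.5.1, and coordinates are on GRCh37. Their order, the MACS2 threshold and control, and the version of the IDR program (irreproducible discovery rate, a measure of how well the ranks of a peak agree between replicates) were not given in the sources used here. Each deposited list came from 1 antibody, genotype and treatment, joined both replicates, and held only peaks matched between them. Its values were the −log10 p of each replicate, at least 3 in every list, and the −log10 of the global IDR, as deposited by the authors. The lists were not limited by IDR: all 24 held peaks with a global IDR over 0.05.

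Peaks with a global IDR of 0.05 or less on chromosomes 1 to 22 and X were analysed, and the number deposited was kept beside them. Overlapping peaks of a list were to be merged, and 0 needed it. Each list held 2 to 9 mitochondrial peaks, and 4 peaks in all lay on other sequences; these were left out. The labels planned 20 M read pairs per library, but the lists carry no read totals, so depth per sample is unknown. The −log10 p of a peak, the authors' own value, served only to rank peaks within a list, by the lower of its 2 replicate values.

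Lists were compared by overlap of 1 bp or more, in both directions, beside the mean of 100 random circular shifts of a list within each chromosome. Shares carry Wilson 95% binomial intervals, which cover counting error only. Each group gave 1 list, so lists were compared without a p-value. The exception was the ratio of peak counts under osimertinib, tested over the 3 genotypes by a two-sided exact sign-flip permutation test of log2 ratios, with Benjamini-Hochberg adjustment over 3 antibodies. The units of that test were the 3 genotypes, so its p-value measures only spread between genotypes. No source says that replicates came from separate cultures. Peaks called WT-only or KO-only were looked up in the Rescue list of the same antibody and treatment. Windows of 1 Mb were compared by their share of all peaks of a list, since list lengths differed.

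The items named by position followed a rule: for 4 comparisons (osimertinib against untreated in WT, KO against WT in each treatment, Rescue against KO under osimertinib) and each antibody, the 5 gained and 5 lost peaks with the highest lower replicate value, and the 5 windows with the largest rise and the 5 with the largest fall. Comparisons, their main tests, this rule and all but 4 of the alternatives were fixed before the data were examined. Further tests and shares chosen after values were seen are named as such where they are given. The alternatives were every deposited peak, a global IDR of 0.01, peaks on an IgG peak left out, covered length, unmerged peaks, overlap of 50% of the shorter peak, the boundaries of each replicate, lists shortened to equal length, and windows of 0.5 Mb and 5 Mb. For peaks left out and for peaks named by position, an IgG peak was any deposited IgG peak of any genotype or treatment, whatever its IDR. No GRCh37 annotation was at hand, so shares in promoters and gene bodies and the 17 gene lists planned were not computed, and no gene was read from a coordinate.

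Regional shifts used every deposited peak in 5 Mb windows, with 2 peaks added per window to both counts, in windows that held 20 peaks or more over the lists compared. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 7. The overlap and window code was tested on simulated data. Overlap shares for 16655 placed regions differed from the known answer by 0 points, but the moved copies were filtered with the same code. A direct search matched 500 of 500 sampled regions. Of 20 simulated windows given 40 extra peaks, 20 came out as the largest rise. The simulated lists were nearly equal in length, unlike many real ones, so this tested the code only.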

Results

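The data were peak lists of H3K27Ac, a mark of active promoters and enhancers, of RAD21, a core cohesin subunit, of PDS5A, a cohesin regulator, and of IgG, the background control. They came from PC9 lung cancer cells of 3 genotypes, untreated or grown under osimertinib. The study asks whether chromatin states linked to METTL7A prepare lung cancer cells for resistance to EGFR inhibitors and for oncogene amplification. The 24 lists held 507516 deposited peaks, each list from 2 replicates. Peaks with a global IDR of 0.05 or less made up 9.86% to 42.9% of the lists of H3K27Ac, RAD21 and PDS5A, and 0.944% to 4.12% of the IgG lists. The −log10 p of a peak correlated between its replicates at a Spearman rho of 0.391 to 0.716 across the peaks of an H3K27Ac, RAD21 or PDS5A list and of 0.0896 to 0.296 across IgG peaks; peaks are not independent replicates. Each condition had 1 list, so no list has a replicate of its own.

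Osimertinib-treated WT cells had more peaks than untreated WT cells for all 3 antibodies. In WT cells H3K27Ac peaks went from 5108 to 10213, RAD21 peaks from 3691 to 16655 and PDS5A peaks from 1757 to 12573, ratios of 2.0, 4.51 and 7.16. KO cells shared the rise for H3K27Ac (5497 to 8511, ratio 1.55) and PDS5A (911 to 4089, ratio 4.49), but their RAD21 peaks went from 5369 to 4372, a ratio of 0.814. Rescue cells changed least in H3K27Ac, from 14445 to 13245 (0.917, and 1.145 over every deposited peak), and in PDS5A, from 14049 to 11466 (0.816). Their RAD21 peaks went from 9188 to 11102 (1.21), a change about as large as that of KO cells but in the other direction. Across genotypes the mean log2 ratio was 0.50 ± 0.57 for H3K27Ac, 0.72 ± 1.29 for RAD21 and 1.57 ± 1.65 for PDS5A (SD, n = 3), with 2 of 3 genotypes up for each antibody. The two-sided exact sign-flip permutation test gave p 0.5, 0.75 and 0.5 for n = 3 genotypes (0.75 for each after adjustment over 3 antibodies), and 0.25 is the smallest p it can give. With 3 genotypes no outcome could reach a smaller p, so the test cannot show a common effect of osimertinib.

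**Figure D1:**
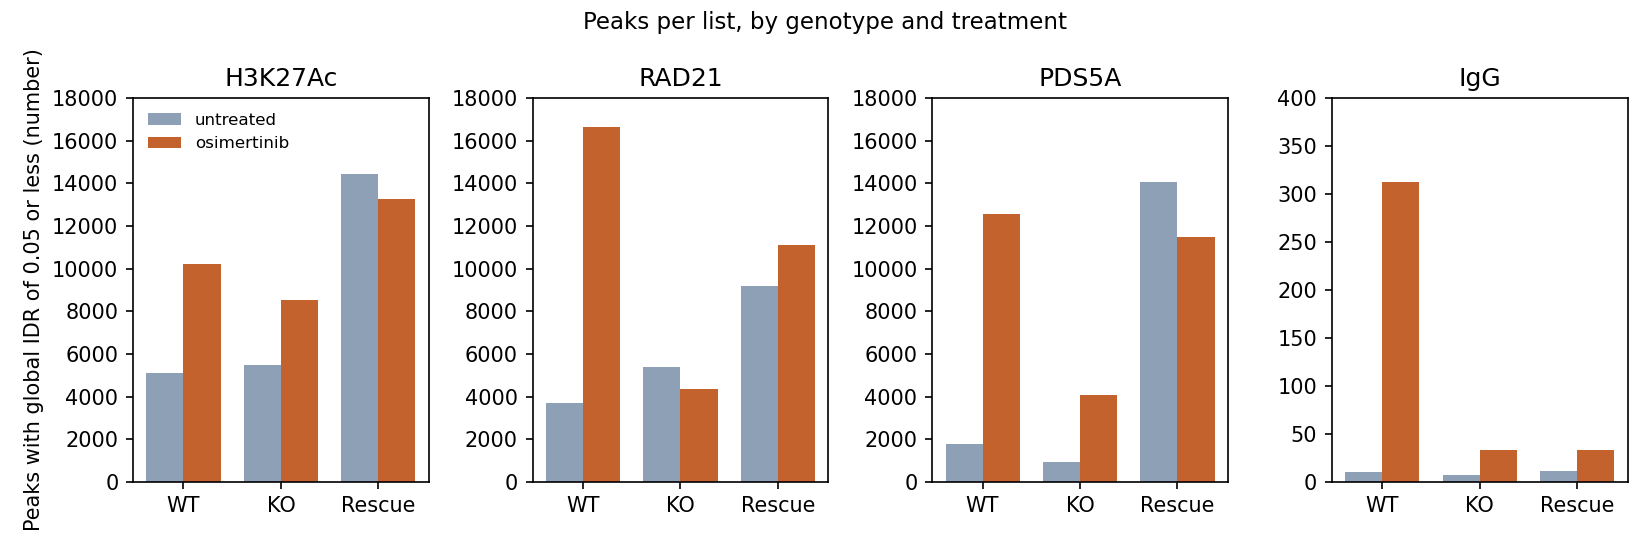
Number of peaks with a global IDR of 0.05 or less in each list (1 list per bar, from 2 replicates), by genotype and treatment, with IgG on its own scale. RAD21 peaks of WT cells rose from 3691 to 16655 under osimertinib while those of KO cells went from 5369 to 4372.

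In each condition the IgG list was shorter than the H3K27Ac, RAD21 and PDS5A lists, but IgG lists grew under osimertinib at the IDR limit. They held 10, 7 and 11 peaks in untreated WT, KO and Rescue cells, and 313, 33 and 33 under osimertinib, so the IgG list of treated WT cells was the longest of the 6. Of those 313 peaks, 69.0% overlapped an H3K27Ac peak of the same cells (95% CI 63.7 to 73.9), 84.0% a RAD21 peak (79.6 to 87.7) and 79.9% a PDS5A peak (75.1 to 83.9). Shifted positions gave 1.64%, 1.78% and 1.64%. In the other direction, 2.12% of H3K27Ac, 1.59% of RAD21 and 1.99% of PDS5A peaks of treated WT cells lay on one of these IgG peaks; over every deposited peak of both lists the shares were 15.02%, 17.51% and 19.27%. Over every deposited peak, IgG lists went from 1057 to 7612 peaks in WT, from 167 to 2703 in KO and from 1051 to 896 in Rescue cells. In WT cells this was a ratio of 7.20, above the 1.95, 2.50 and 2.42 of H3K27Ac, RAD21 and PDS5A. Among deposited peaks, the IgG list of treated WT cells held most in a window on chromosome 16 from 30 to 31 Mb (43 of 7612). That of treated KO cells held most on chromosome 19 from 58 to 59 Mb (29 of 2703).

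In treated WT cells most peaks of untreated WT cells were still present. Many peaks that treated WT cells added overlapped a deposited untreated peak over the IDR limit. Of the untreated peaks, 62.9% of H3K27Ac (95% CI 61.6 to 64.2), 87.8% of RAD21 (86.7 to 88.8) and 85.8% of PDS5A (84.1 to 87.4) overlapped a treated peak. Of the treated peaks, 68.5% of H3K27Ac, 80.6% of RAD21 and 88.0% of PDS5A had no untreated counterpart. Of these added peaks, 2568 of 6995 for H3K27Ac, 6960 of 13420 for RAD21 and 4568 of 11069 for PDS5A met no deposited untreated peak whatever its IDR, which is 25.1%, 41.8% and 36.3% of all treated peaks. In KO cells the corresponding shares were 8.94%, 3.48% and 26.8%, and in Rescue cells 2.08%, 5.34% and 1.28%. Shifting a list gave overlaps of treated WT peaks with untreated ones of 0.762%, 0.337% and 0.181%.

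The strongest RAD21 peaks that treated WT cells added included 3 positions with no deposited peak before treatment, each also carrying PDS5A and none on an IgG peak. They lay on chromosome 5 from 169407092 to 169408111 (lower replicate −log10 p 212, GRCh37), chromosome 19 from 40283552 to 40284113 (159.8) and chromosome 20 from 23779990 to 23780756 (156). Among the H3K27Ac peaks gained, those on chromosome 5 from 29795968 to 29796823 (−log10 p 60.8) and from 29191374 to 29192433 (57.3) lay within 1 Mb of each other, and the former had no deposited peak before treatment, while the latter overlapped an IgG peak. The strongest PDS5A peak gained was on chromosome 7 from 5601501 to 5603628 (137). An untreated peak over the IDR limit was deposited there, and an IgG peak overlapped. RAD21 was lost on chromosome 20 from 39317397 to 39319405 (82.9 in untreated WT cells), with no deposited peak under osimertinib. In treated KO cells RAD21 was present there, from 39317233 to 39319499 (67.1), together with H3K27Ac and PDS5A. RAD21 on chromosome 8 from 128747099 to 128752175 (86.3) left the list of treated WT cells. A deposited peak over the IDR limit remained there, and an IgG peak overlapped this position. Of the 120 peaks that the naming rule gave over all comparisons, 84 overlapped an IgG peak and 9 had no deposited peak in the other list. These IgG peaks were deposited in any genotype or treatment, whatever their IDR, so the overlap need not be in the cells named.

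By window, H3K27Ac peaks gathered in a few places in treated WT cells. On chromosome 5 from 14 to 15 Mb they went from 4 to 29, on chromosome 7 from 116 to 117 Mb from 2 to 20, on chromosome 2 from 121 to 122 Mb from 3 to 22 and on chromosome 22 from 36 to 37 Mb from 3 to 22. KO and Rescue cells did not share the rises on chromosomes 5 and 7: on chromosome 5 they had 5 and 6 peaks untreated and 6 and 7 under osimertinib, and on chromosome 7 they had 2 and 4 untreated and 2 and 4 under osimertinib. Deposited IgG peaks of WT cells went from 1 to 11 in the window on chromosome 5 and from 1 to 7 in that on chromosome 7. As shares of all deposited IgG peaks these were 0.0946% to 0.145% and 0.0946% to 0.0920%. The H3K27Ac share in the window on chromosome 7 went from 0.0392% to 0.196%. On chromosomes 2 and 22 treated KO cells also had more H3K27Ac peaks than untreated ones, 10 against 1 and 10 against 2, while Rescue cells had 11 against 12 and 14 against 25. Both windows held 10 deposited IgG peaks in treated and 0 in untreated WT cells. For cohesin, chromosome 17 from 73 to 74 Mb rose from 2 to 30 RAD21 peaks and from 0 to 27 PDS5A peaks, and from 74 to 75 Mb from 1 to 24 and from 0 to 27. Deposited IgG peaks of WT cells rose there as well, from 2 to 23 and from 2 to 14. As shares of all deposited IgG peaks these were 0.189% to 0.302% and 0.189% to 0.184%, so only the former rose. From 73 to 74 Mb the RAD21 and PDS5A shares did not rise over every deposited peak, where they differed by -0.0258 points for RAD21 and -0.0151 points for PDS5A. The falls in share lay in peak-dense windows whose counts did not fall much, as on chromosome 20 from 48 to 49 Mb, with 30 H3K27Ac peaks before and after but a share of 0.587% against 0.294%.

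Untreated KO cells had about as many H3K27Ac peaks as untreated WT cells, more RAD21 peaks and fewer PDS5A peaks. Untreated KO cells had 1.08 times the H3K27Ac peaks of WT cells, a ratio that fell below 1 when peaks on IgG peaks were left out (0.965) or covered length was compared (0.990). RAD21 had a ratio of 1.45 and PDS5A of 0.518. Of the peaks of untreated WT cells, 36.5% of H3K27Ac, 23.6% of RAD21 and 62.9% of PDS5A were absent from KO cells. Few had no deposited KO peak at all, namely 1.74%, 2.49% and 13.4%. The strongest H3K27Ac peak that only KO cells had lay on chromosome 7 from 55200053 to 55202932 (−log10 p 109.98, 2880 bp wide). RAD21 was also present there, WT cells had a deposited peak over the IDR limit, and an IgG peak overlapped. The PDS5A peaks on chromosome 8 from 142085228 to 142086503 (55.2) and chromosome 19 from 45942657 to 45943398 (52.8) of untreated WT cells, both with RAD21, had no deposited peak in KO cells. Chromosome 17 from 7 to 8 Mb held 9 PDS5A peaks in untreated WT cells and 1 in KO cells, and 9 and 0 deposited IgG peaks.

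Under osimertinib WT and KO cells differed more in the number of RAD21 and PDS5A peaks than in that of H3K27Ac peaks. Treated KO cells had 0.263 times the RAD21 peaks and 0.325 times the PDS5A peaks of treated WT cells, against 0.833 times the H3K27Ac peaks (1.096 at a global IDR of 0.01 or less). Of the RAD21 peaks of treated KO cells, 88.1% (95% CI 87.1 to 89.1) also lay in WT cells, and of PDS5A peaks 81.8% (80.6 to 83.0). The WT lists were longer, with 16655 RAD21 and 12573 PDS5A peaks against 4372 and 4089 in KO cells, which raises these shares. In the other direction 77.0% of RAD21 and 73.5% of PDS5A peaks of treated WT cells were absent from KO cells, and 34.3% and 26.9% met no deposited KO peak. The H3K27Ac lists were closer in length, with 10213 WT and 8511 KO peaks. Of these, 55.4% of WT peaks were absent from KO cells and 46.4% of KO peaks from WT cells. With the WT and KO lists of an antibody cut to the shorter of them, the share of WT peaks absent from KO cells changed. It was 51.83% for H3K27Ac (8511 peaks), 48.88% for RAD21 (4372) and 52.19% for PDS5A (4089). These lengths differ between antibodies, so the shares do not compare them. RAD21 on chromosome 2 from 223182753 to 223185341 (−log10 p 221) was among the strongest WT peaks absent from treated KO cells. So were RAD21 on chromosome 3 from 156391447 to 156394247 (198) and PDS5A on chromosome 2 from 222435377 to 222439717 (252). Each met a deposited KO peak over the IDR limit and lay on an IgG peak. Chromosome 7 from 73 to 74 Mb had 28 RAD21 peaks in treated WT cells and 0 in KO cells, and chromosome 7 from 128 to 129 Mb had 18 PDS5A peaks against 0. Deposited IgG peaks numbered 14 against 1 and 10 against 0 in these windows. H3K27Ac was more frequent in KO cells on chromosome 20 from 62 to 63 Mb (20 peaks against 4) and chromosome 8 from 22 to 23 Mb (15 against 3).

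Rescue cells, in which METTL7A was put back, had more H3K27Ac, RAD21 and PDS5A peaks than KO cells in each treatment. Untreated Rescue cells had 2.63 times the H3K27Ac peaks, 1.71 times the RAD21 peaks and 15.4 times the PDS5A peaks of KO cells, and under osimertinib the ratios were 1.56, 2.54 and 2.80. Over every deposited peak the untreated PDS5A ratio was 3.64. In treated cells, RAD21 on chromosome 3 from 156391523 to 156394169 (−log10 p 179) and PDS5A on chromosome 2 from 222435633 to 222439586 (123) were again in the Rescue list, at positions listed in WT but not in KO cells. So was PDS5A on chromosome 20 from 4201493 to 4202813 (167). All 3 overlapped an IgG peak and a deposited KO peak over the IDR limit. RAD21 went the other way at that position of chromosome 2. Its peak from 222435331 to 222439164 (79.9) was in the treated KO list but not in the Rescue list, where a deposited peak remained. Chromosome 1 from 155 to 156 Mb had 31 H3K27Ac and 26 RAD21 peaks in treated Rescue cells against 11 and 4 in KO cells, while treated WT cells had 8 and 19; over every deposited peak the Rescue share there was not above that of KO cells, at -0.00871 and -0.0214 points. PDS5A peaks on chromosome 1 from 110 to 111 Mb numbered 27 in Rescue, 3 in KO and 19 in WT cells, and deposited IgG peaks 2, 2 and 11.

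Under the IDR limit of 0.05, for no antibody did the Rescue list hold a larger share of WT-only than of KO-only peaks beyond the 95% intervals. Untreated H3K27Ac was an exception over every deposited peak, where the WT-only share exceeded the KO-only share by 25.15 points. In untreated cells the Rescue list held 75.8% of WT-only and 77.6% of KO-only H3K27Ac peaks, 75.1% and 77.6% of RAD21 peaks, and 90.8% and 88.9% of PDS5A peaks, with overlapping 95% intervals for each antibody. Under osimertinib it held 35.0% (33.7 to 36.2) of WT-only against 67.8% (66.3 to 69.3) of KO-only H3K27Ac peaks. For RAD21 these were 39.8% (38.9 to 40.6) against 77.8% (74.1 to 81.2), and for PDS5A 51.8% (50.8 to 52.8) against 75.2% (72.0 to 78.2). Under osimertinib, strong WT-only peaks were found more often than weak ones: over the lowest, middle and highest parts by signal, the Rescue list held 25.8%, 37.4% and 56.0% of the treated WT-only RAD21 peaks and 37.6%, 48.6% and 69.2% of the PDS5A peaks. For WT-only peaks of untreated cells the shares differed little by strength, with 76.5%, 76.5% and 74.4% for H3K27Ac, 74.1%, 74.1% and 76.9% for RAD21 and 90.2%, 91.0% and 91.1% for PDS5A. KO-only peaks also rose with strength in part, from 70.1% to 76.4% and 86.3% for untreated RAD21 and from 57.6% to 69.4% and 76.5% for treated H3K27Ac. WT-only peaks were far more numerous than KO-only ones under osimertinib, with 12824 against 519 for RAD21, of which the Rescue list held 5098 and 404. With lists of equal length the treated differences shrank to -28.66 points for H3K27Ac, -23.0 for RAD21 and -8.177 for PDS5A. Rescue cells are knockout cells that overexpress METTL7A, so KO-only peaks are no neutral measure for peaks that return. These shares therefore cannot tell whether METTL7A restores peaks.

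**Figure D2:**
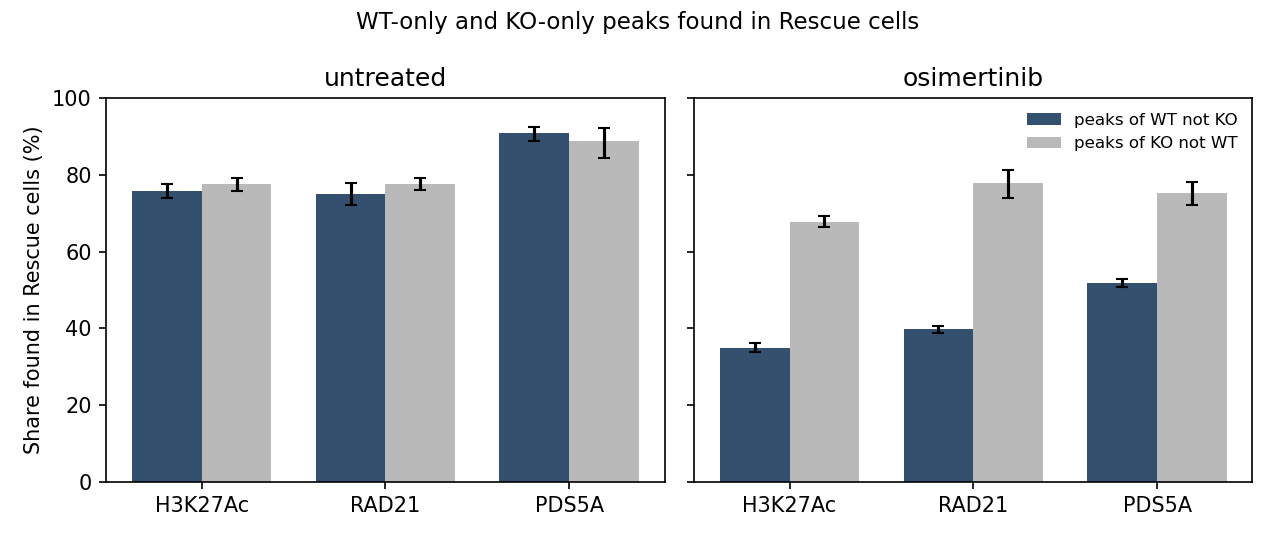
Share (%) of peaks that only WT or only KO cells had that were found in Rescue cells, by antibody and treatment, with 95% Wilson intervals as error bars. Under osimertinib the WT-only share was 35.0% to 51.8% and the KO-only share 67.8% to 77.8%.

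Among the RAD21 and PDS5A peaks that treated WT cells gained, treated Rescue cells held more than treated KO cells did, and for H3K27Ac this depended on the IDR limit. Of 13420 RAD21 peaks gained, 11.8% (95% CI 11.2 to 12.3) were present in treated KO cells and 41.9% (41.0 to 42.7) in treated Rescue cells. Of 11069 PDS5A peaks these shares were 19.3% and 57.9%, and of 6995 H3K27Ac peaks 31.6% and 44.7%. Against every deposited peak of the treated KO and Rescue lists, the shares were 58.3% and 75.7% for RAD21, 69.8% and 86.7% for PDS5A, and 78.0% and 77.4% for H3K27Ac. Untreated Rescue cells already had 33.0% of the RAD21, 64.0% of the PDS5A and 49.5% of the H3K27Ac peaks gained, where untreated KO cells had 15.3%, 1.91% and 16.5%. The untreated KO list of PDS5A held only 911 peaks, too few to hold most of the 11069 gained. Against every deposited peak the untreated Rescue shares were 73.0%, 91.6% and 79.4%, and the untreated KO shares 60.5%, 38.4% and 60.2%. Peaks gained in WT cells that treated Rescue but not KO cells had made up 31.6% for RAD21, 40.8% for PDS5A and 19.8% for H3K27Ac, and those that KO but not Rescue cells had made up 1.55%, 2.16% and 6.68%. Neither had 56.6% of RAD21, 39.9% of PDS5A and 48.6% of H3K27Ac peaks gained. The Rescue lists were longer than the KO lists, which raises their shares.

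**Figure D3:**
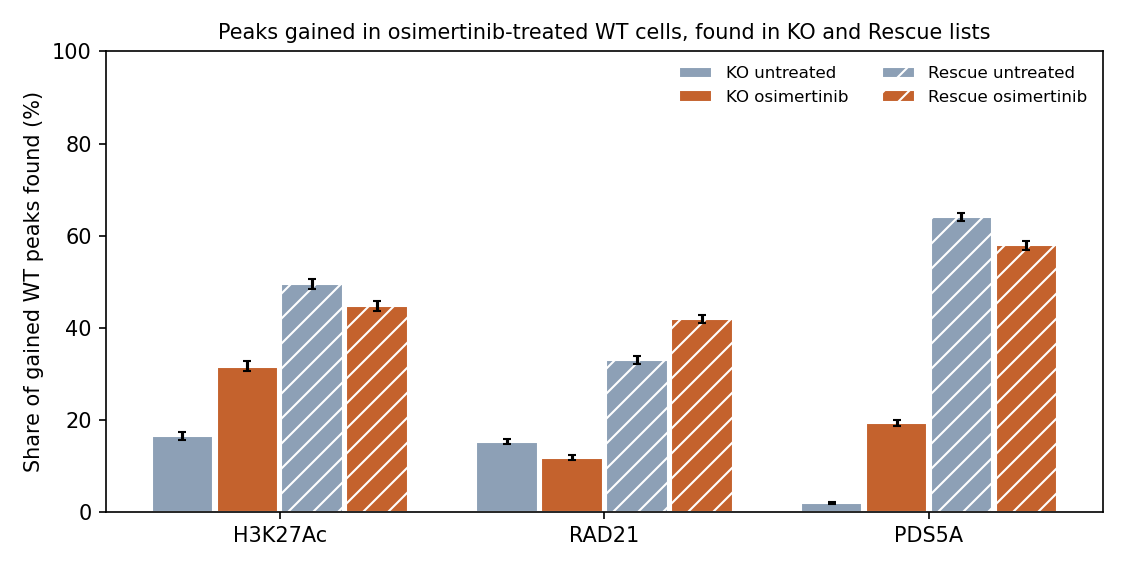
Share (%) of the peaks gained in osimertinib-treated WT cells that the KO and Rescue lists also held, by antibody, with 95% Wilson intervals as error bars. For PDS5A, untreated Rescue cells had 64.0% and untreated KO cells 1.91%, from lists of 14049 and 911 peaks. Against every deposited peak these shares were 91.6% and 38.4%.

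PDS5A and RAD21 lay together far more often than shifted peaks did, and how their overlap moved with treatment depended on list length. The share of PDS5A peaks on a RAD21 peak went from 62.1% (95% CI 59.8 to 64.3) to 77.5% (76.8 to 78.2) in WT cells but from 74.2% (71.3 to 76.9) to 59.2% (57.7 to 60.7) in KO cells. In Rescue cells it went from 7025 of 14049 peaks (95% CI 49.2 to 50.8%) to 64.8% (63.9 to 65.7). Over every deposited peak the KO share went from 80.28% to 74.92%. The lists of all conditions were also shortened to 911 peaks, an alternative added after the data were seen. The share then went from 40.61% to 43.69% in WT, from 37.43% to 46.98% in KO and from 38.2% to 42.37% in Rescue cells. No intervals were computed at this length, so the smaller differences, in WT and Rescue cells, cannot be told from counting error. The share of RAD21 peaks with PDS5A went from 29.7% to 58.7% in WT cells, from 12.7% to 55.5% in KO cells and from 77.0% to 67.4% in Rescue cells. At 911 peaks these were 40.72% to 43.69%, 37.43% to 46.98% and 38.2% to 42.37%, so the rises shrank and the fall in Rescue cells was not seen. The same limit holds for the WT and Rescue differences. RAD21 peaks with PDS5A numbered 1095 and 9773 in untreated and treated WT cells, 680 and 2427 in KO cells, and 7071 and 7483 in Rescue cells. The share of H3K27Ac peaks with RAD21 went from 21.6% to 47.9% in WT cells and from 29.2% to 39.4% in Rescue cells (39.21% to 37.36% over every deposited peak), but from 32.3% (1776 of 5497 peaks) to 1957 of 8511 peaks (95% CI 22.1 to 23.9%) in KO cells. With lists shortened to 3691 peaks that share went from 23.65% to 16.77% in WT, from 27.28% to 27.66% in KO and from 25.44% to 28.04% in Rescue cells, so these directions also depend on list length. RAD21 peaks that carried both PDS5A and H3K27Ac went from 350 to 3079 in WT cells, from 177 to 1219 in KO cells and from 3246 to 3588 in Rescue cells. Shifted peaks overlapped at 0.0816% to 2.02% in these comparisons, and a longer list of the partner raises each share.

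**Figure D4:**
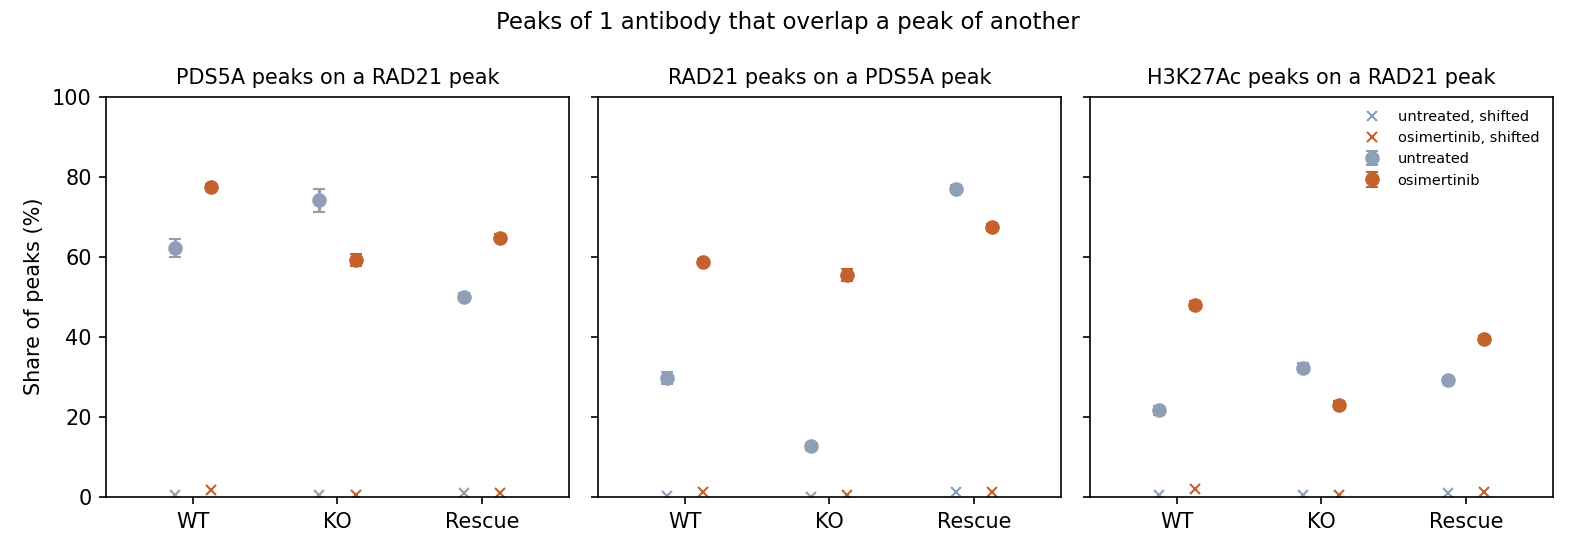
Share (%) of the peaks of an antibody that overlap a peak of another in the same cells, by genotype and treatment, with 95% Wilson intervals as error bars and crosses for the mean of 100 shifted lists. The share of PDS5A peaks on RAD21 rose under osimertinib in WT (62.1% to 77.5%) and Rescue cells and fell in KO cells (74.2% to 59.2%), but rose in KO cells with lists of 911 peaks (37.43% to 46.98%).

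Over wider windows, chosen after their values were seen, treated WT cells gained share in some chromosome segments and lost it in others, by the mean of the 3 antibodies. Of 573 windows of 5 Mb over every deposited peak, 25 had a mean log2 ratio of shares, osimertinib over untreated, of 1 or more and 7 of -1 or less. The 3 antibodies shared their direction in each of these, but in only 335 of all 573 windows (58.5%). Rises lay on chromosome 5 from 20 to 30 Mb (2.2 from 25 to 30 Mb), chromosome 3 from 60 to 65 Mb (1.88), chromosome X from 50 to 55 Mb (1.78), chromosome 7 from 115 to 120 Mb (1.23) and from 120 to 125 Mb (1.68), and along chromosome 6 from 90 to 120 Mb, with 1.32 from 90 to 95 Mb but 0.52 from 105 to 110 Mb. Falls lay on chromosome 14 from 85 to 90 Mb (-2.44) and from 95 to 100 Mb (-2.49) and on chromosome 18 from 75 to 80 Mb (-1.33). The window on chromosome 7 from 115 to 120 Mb shifted by -0.07 in KO and -0.57 in Rescue cells.

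**Figure D5:**
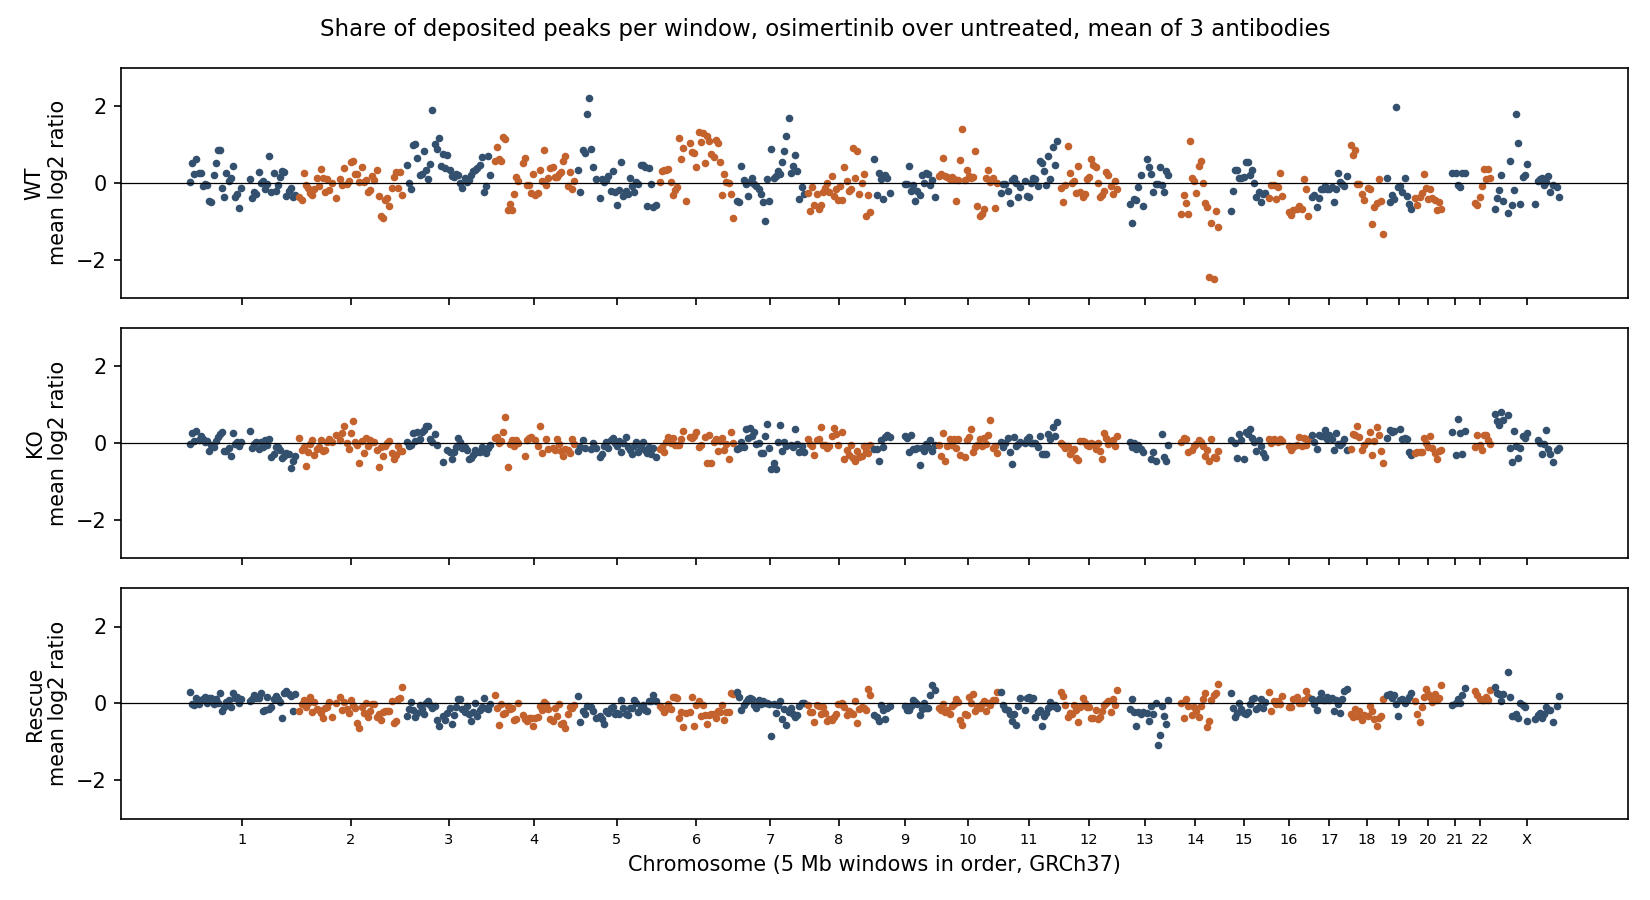
Log2 ratio of the share of deposited peaks per 5 Mb window, osimertinib over untreated, as the mean of H3K27Ac, RAD21 and PDS5A, along the chromosomes (1 point per window) in WT, KO and Rescue cells. WT cells reached 2.2 on chromosome 5 and -2.49 on chromosome 14.

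The number of positions shared by all 6 conditions was bounded by the shortest list, which held 5108 H3K27Ac, 3691 RAD21 or 911 PDS5A peaks. Of 21808 H3K27Ac positions, 1417 were in all 6 lists, of 20000 RAD21 positions 1754, and of 19353 PDS5A positions 436. Treated WT cells alone had 6451 RAD21, 2807 PDS5A and 2648 H3K27Ac positions, while untreated Rescue cells alone had 620, 2978 and 2779. Treated KO cells alone had 33 RAD21, 33 PDS5A and 477 H3K27Ac positions.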

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

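The shares of the strongest peaks of other conditions, set beside those of treated WT cells, were chosen only after the result was seen, and no other test here was. Each difference named here came from genotypes or treatments whose single lists moved in opposite directions, and the difference was not tested.

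Peak counts answered osimertinib in opposite directions between genotypes. For H3K27Ac, WT cells rose 2.0-fold and KO cells 1.55-fold where Rescue cells had a ratio of 0.917, so the WT ratio was 2.181 times and the KO ratio 1.689 times the Rescue ratio. For PDS5A, the WT ratio of 7.16 was 8.768 times and the KO ratio of 4.49 was 5.50 times the Rescue ratio of 0.816. For RAD21, WT cells had a ratio of 4.51 and KO cells of 0.814, which is 5.541 times, and the KO ratio was 0.6739 times that of Rescue cells. Seen between treatments, the KO to WT ratio of RAD21 was 1.45 untreated and 0.263 under osimertinib, again 5.541 times, and that of H3K27Ac 1.08 and 0.833, or 1.291 times. Over every deposited peak the PDS5A ratios were 2.416 in WT, 1.988 in KO and 0.809 in Rescue cells, and the RAD21 ratios 2.501 in WT and 0.931 in KO cells, so these differences kept their direction and shrank. The H3K27Ac ratios were then 1.950 in WT, 1.655 in KO and 1.145 in Rescue cells, so only the opposite direction of Rescue cells rests on the IDR limit. The KO to WT difference of H3K27Ac also changed direction with the setting, to 0.9654 untreated without peaks on IgG peaks and to 1.096 treated at a global IDR of 0.01 or less.

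The lists of all 3 antibodies grew in treated WT cells, and greater depth alone, which would bring weaker copies of known sites over the threshold, was argued against as the whole cause: of the 1000 strongest treated peaks, 8.80% of H3K27Ac, 14.6% of RAD21 and 9.10% of PDS5A peaks met no deposited peak before treatment, against 0%, 0.2% and 0% in Rescue cells. The same untreated WT lists lacked 0.3%, 2.7% and 2.5% of the strongest peaks of treated KO cells. KO cells had 11.5% for PDS5A, where the untreated KO list also lacked 9.2% to 11.4% of the strongest peaks of untreated WT cells and of Rescue cells, so a poor list can give such values, and fewer reads or poorer enrichment before treatment stay open for part of the growth. Background that IgG also yields in these cells cannot be told apart from a gain: 28.11% of gained H3K27Ac, 23.9% of RAD21 and 28.1% of PDS5A peaks overlapped a deposited IgG peak, but kept peaks did so more often (54.0%, 44.6% and 43.8%). A change of chromatin under osimertinib in WT cells may also contribute and was not tested apart from these.

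RAD21 sites of treated WT cells were largely missing from treated KO cells. A weaker RAD21 library from KO cells was argued against as the whole cause, since 9.70% (95% CI 8.02 to 11.7) of the 1000 strongest WT peaks met no deposited KO peak, while the same KO list lacked 0.9% to 1.7% of the strongest peaks of the 4 other conditions. For part of the missing sites it stays open, since the RAD21 share absent fell from 77.0% to 48.88% with WT and KO lists cut to 4372 peaks. H3K27Ac had 51.83% at 8511 peaks, a different length, so these values cannot tell whether RAD21 stood out. Sites that WT cells carry alone, whatever METTL7A does, cannot be told apart from sites that need METTL7A: 4.20% (3.12 to 5.63) of the same peaks had no deposited peak in Rescue cells, fewer than in KO cells but with an interval too wide for the bound set. A METTL7A-dependent part of the RAD21 gain could therefore be no more than a hypothesis, and clonal differences between the lines stay open and were not tested.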

How the results depend on the processing

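Of 1429 alternative values for 235 results, 803 stayed within the counting error or within 1.5 times of the value given, 619 moved further, and 7 reversed a ratio, or a difference or correlation whose interval excluded 0. A further 13 differences whose interval spanned 0 also changed sign, 2 of recovery and 11 of windows, which makes 20 in all. Of the ratios of peak counts, 91 of 105 stayed within 1.5 times in the same direction. These include 21 values from unmerged peaks, which could not differ, since 0 peaks needed merging. Ratios also gave 4 of the 7 reversals. For windows, 201 of 240 values stayed within the counting error, which is a different limit. The boundaries of either replicate, an overlap of 50% of the shorter peak and windows of 0.5 Mb changed no result past its limits. The alternatives that asked for no deposited peak in the other list, and that limited regional correlations by IDR, were chosen only after the result was seen, as were the co-occupancy of kept and gained peaks apart and that at 1 common length. The cause was not tested, except that a longer list contains more of the peaks of another by construction. No paired analysis was possible because each list already joins both replicates, and for the same reason leaving out a replicate gives no value. Promoter shares and gene lists were not run, for want of a GRCh37 annotation. Depth limits each list length, and no read totals tell by how much.

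The 7 reversals were these. The Rescue ratio of H3K27Ac under osimertinib became 1.145 over every deposited peak. The KO to WT ratio of H3K27Ac became 0.9654 without peaks on IgG peaks and 0.9905 by covered length in untreated cells, and 1.096 at a global IDR of 0.01 or less in treated cells. The lowest regional correlation between antibodies for untreated KO against WT cells went from -0.155 to 0.0694 on peaks with a global IDR of 0.05 or less. On chromosome 19 from 58 Mb, the H3K27Ac share of treated KO minus WT cells went from 0.157 to -0.0268 points without peaks on IgG peaks. On chromosome 20 from 48 Mb, the RAD21 share of treated Rescue minus KO cells went from -0.205 to 0.0853 points over every deposited peak.

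Over every deposited peak the larger count ratios shrank. Osimertinib against untreated became 2.501 for WT RAD21, 2.416 for WT PDS5A and 1.988 for KO PDS5A. KO against WT under osimertinib became 0.4555 for RAD21 and 0.5276 for PDS5A. Rescue against KO became 1.668 for untreated H3K27Ac (3.965 without peaks on IgG peaks), 3.639 for untreated PDS5A, and 1.488 and 1.481 for treated RAD21 and PDS5A.

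The share of treated WT peaks absent from untreated WT cells (68.5% of H3K27Ac, 80.6% of RAD21, 88.0% of PDS5A) became 57.66%, 63.58% and 62.47% over every deposited peak, 79.6%, 86.25% and 90.76% without peaks on IgG peaks, and 56.54%, 49.82% and 54.52% with lists of equal length. It became 25.14%, 41.79% and 36.33% where no deposited peak was allowed in the other list, and at a global IDR of 0.01 or less 85.04% for RAD21 and 90.93% for PDS5A. The share absent from treated KO cells (55.4%, 77.0% and 73.5%) became 41.7%, 58.64% and 53.16% over every deposited peak, 59.23%, 82.18% and 79.29% at an IDR of 0.01 or less, 69.96%, 84.22% and 80.51% without peaks on IgG peaks, 51.83%, 48.88% and 52.19% with equal lengths, and 15.22%, 34.31% and 26.9% where no deposited peak was allowed.

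The recovery in Rescue cells, WT-only minus KO-only share, kept its sign in treated cells. Over every deposited peak it was -40.69 points for H3K27Ac, -32.44 for RAD21 and -31.3 for PDS5A, and with equal lengths -28.66, -23.0 and -8.177. PDS5A gave -18.02 at an IDR of 0.01 or less. In untreated cells, where the differences were -1.76, -2.56 and 1.88 points, every deposited peak gave 25.15 for H3K27Ac and -11.11 for RAD21, and equal lengths gave -9.545 for RAD21 and -8.487 for PDS5A.

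The share of PDS5A peaks on RAD21, for untreated and treated cells in turn, became 70.52% and 83.99% in WT, 80.28% and 74.92% in KO, and 65.19% and 77.28% in Rescue cells over every deposited peak. Without peaks on IgG peaks it became 49.89% and 73.66%, 65.29% and 48.65%, and 42.31% and 55.69%. At an IDR of 0.01 or less it became 76.1% in treated WT, 69.97% and 57.61% in KO, and 43.48% and 58.89% in Rescue cells. With equal lengths it became 42.69% and 66.31% in WT and 37.43% and 56.91% in KO cells, and 60.26% in untreated Rescue cells. Lengths were equal only within a condition, shorter in untreated than in treated KO cells, so these values do not compare treatments. At 1 common length for all conditions (911 peaks) it became 40.61% and 43.69% in WT, 37.43% and 46.98% in KO, and 38.2% and 42.37% in Rescue cells, so the fall in KO cells depends on list length. The IgG peaks of treated WT cells lay on H3K27Ac, RAD21 and PDS5A peaks at 90.09%, 92.72% and 91.15% over every deposited peak and at 40.91%, 76.36% and 62.73% at an IDR of 0.01 or less.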

Other observations

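The regional pattern in treated WT cells was noticed in the data, and the test with alternating blocks, the correlation between neighbouring windows, the regression of the IgG ratio on density, the windows named and the co-occupancy of kept and gained peaks apart were chosen only after the result was seen.

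Osimertinib-treated WT cells shifted their peaks by region, and the shifts of H3K27Ac, RAD21 and PDS5A were correlated, although all 3 shared their direction in only 335 of 573 windows (58.5%). Over 573 windows of 5 Mb, the log2 ratio of peak shares, treated over untreated, correlated between antibodies at r 0.593 to 0.724, against 0.0197 to 0.171 in KO cells (550 windows) and 0.436 to 0.585 in Rescue cells (572). At a global IDR of 0.05 or less, an alternative added after the result was seen, r was 0.427 to 0.576 in WT cells (496 windows). It was then 0.157 to 0.177 in KO cells (383) and 0.242 to 0.354 in Rescue cells (528). Windows are not independent replicates. After regression on peak density, the mean shift of the 3 antibodies in a window of WT cells correlated with that of the next at 0.480 (534 windows). The windows that shifted most included chromosome 5 from 20 to 30 Mb, chromosome 6 from 90 to 105 Mb and from 110 to 120 Mb, chromosome 7 from 115 to 125 Mb and chromosome 14 from 85 to 90 Mb and from 95 to 100 Mb.

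A change in DNA copy number, which every library of these cells would carry, is a candidate explanation for these regional shifts. The IgG ratio of treated WT cells over the other IgG lists correlated with the mean shift at r 0.5082, and at 0.543 after both were regressed on peak density. IgG peaks also lie on sites the antibodies bind, so this does not settle the cause. A bias between peak-dense and peak-poor regions was argued against, as the lowest correlation after regression on density was 0.5885. The same sites counted under several antibodies remained undecided on unshared peaks, where the lowest correlation was 0.02137. That value is the low one set beforehand for this explanation, but leaving out shared peaks takes more from the longer treated lists, whose unshared share fell from 52.3% to 45.4% for H3K27Ac and from 20.7% to 10.2% for PDS5A. Read in alternating 100 kb blocks that the antibodies of a pair did not share, the lowest correlation was 0.4392, which argues against shared sites alone. Broad chromatin changes of the treated WT cells could give the same pattern, and whether its near absence in KO cells has to do with METTL7A was not tested. The 25 windows with a mean log2 shift of 1 or more held 2.64% of gained H3K27Ac, 2.73% of RAD21 and 2.16% of PDS5A peaks, so they account for little of the growth of the lists.

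RAD21 peaks that WT cells kept under osimertinib were wider than those gained, with medians of 1332 and 941 bp. PDS5A lay on 80.3% (95% CI 78.9 to 81.7) of the RAD21 peaks kept and 53.5% (52.6 to 54.3) of those gained. RAD21 lay on 62.4% of the H3K27Ac peaks that WT cells kept and 41.2% of those gained. In KO cells the same shares were 31.7% and 15.9%, and in Rescue cells 45.3% and 24.7%. H3K27Ac lay on 28.6% of the PDS5A peaks kept and 45.8% of those gained in KO cells, so the order turned. In Rescue cells these were 36.9% and 43.7%, but in WT cells 34.6% and 28.2%. None of these shares was adjusted for peak width.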
